A study of Homo sapiens with 8 samples.

How the data were processed

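The series followed nascent transcription in IMR90 cells, a human lung fibroblast line, that were either proliferating or had reached replicative senescence after serial passage. Run-on libraries of 2 kinds were made. PRO-seq maps engaged RNA polymerases by letting them extend their transcripts over a few biotin-labelled bases, and PRO-cap selects the capped 5′ ends of the same transcripts, so that each read marks a start of transcription. The 8 samples fell into 4 groups by their labels. There was 1 PRO-seq library of proliferating cells at population doubling 20 and 1 of senescent cells at population doubling 76. The 3 PRO-cap libraries of proliferating cells came from population doubling 23 (replicate 1) and 26 (replicates A and B), and the 3 of senescent cells from population doubling 76 (replicate 1) and 67 (replicates A and B).

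The data analysed here were 4 deposited site lists, of which 2 were distinct, because each list was deposited both for the whole series and, with identical content, for replicate 1 of one PRO-cap group. One list held sites of proliferating cells and the other sites of senescent cells. PRO-seq values and values per library were not analysed here. The deposited value of a site is a fold, a ratio of one state over the other, as the authors computed it; the direction was taken from the name of the list. How the sites were called, which libraries entered, whether replicates were pooled and which cutoffs were set is not given in the sources used here. Per the submitters' processing notes, BWA 0.7.10, SAMtools 1.1, cutadapt 2.10, bedtools 2.27.1-65 and HOMER were used, with no role given for any of them. The notes name hg19 among the builds and the lists are named for it.

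Every site was 150 bases wide and had + in its strand column, so width and strand could not be compared and the planned tests that need a strand from the files (orientation and stranded overlap) could not be run from that column. The folds carried information on depth. In each list they equalled a whole number of reads times a fixed step, plus a pseudocount of 1, divided by the same quantity for the other state. With a step of 39.4 per read for proliferating and 32.8 for senescent cells, all 400 and 849 deposited folds were matched by whole reads. The tolerance was 1e-06 of a read, and 0.02% and 0.01% of 10000 random folds were matched within it. A single step per state is what 1 library, or several merged before scaling, would give. Reads per site were taken from this decoding. If both states were scaled to the same total, the steps put the senescent data at 1.2 times the depth of the proliferating data. The total depth of each library is not given in the sources used here.

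Sites were compared with the GRCh37 primary assembly, which has the coordinates of hg19 on the chromosomes used, and with GENCODE 44 lifted to it. No site lay past a chromosome end (0 of 1249). Each site took 1 class by its midpoint, in the order promoter (within 1 kb of an annotated transcript start), exon, intron and intergenic. Shares carry Wilson 95% intervals. Classes, chromosomes and motifs were compared between the lists by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment within each family, medians by permutation tests with 100000 resamples of list labels, and the number of sites by an exact two-sided binomial test against an equal split. Sites were also set against 1000 seeded random placements on their own chromosome, and, chosen after the data were examined, against 1000 placements past the midpoint of protein-coding genes at least 5 kb from gene 5′ ends. Intervals and p-values count sites, cover counting error only and say nothing of the spread between cultures, because the lists hold no value per library. Sites lay in clusters and were not independent, so p-values over sites are too small.

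Base composition and motifs were read in the 200 bases centred on a site. To weigh composition, each site's 200 bases were shuffled 200 times with every dinucleotide count kept, an analysis chosen after the data were examined, with an interval over shuffles only. The motifs were AP-1 (TGASTCA, where S is C or G), a TATA box (TATAWA, where W is A or T) and an initiator (BBCABW). The initiator test was void, since nearly every site had a match (849 of 849 and 399 of 400). The 9 gene lists and the rule for named genes were set before the data were examined. Named are, for each list, the 10 genes with the most sites, the 10 sites with the highest fold, and each member of a gene list with at least 2 sites of one list or a site of each. A gene held a site that lay within it or within 1 kb upstream. Gene lists were tested by Fisher's exact test and against 10000 random lists of protein-coding genes matched on length. Of the planned members, DDX58 and PECAM1 had no match in the annotation. Some genes that the rule would name are not reported here.

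Alternatives set before the data were examined joined sites within 500 bases, kept autosomes or the 50% of each list with the highest fold, changed the promoter to 500 bases or 2 kb, used protein-coding genes only or any overlapping base, required 50% reciprocal overlap, placed sites within 1 Mb, read 500 bases of sequence, widened genes by 50 kb or dropped promoter sites, summed bases in place of sites, and left out each chromosome in turn. Alternatives added later joined sites within 10 kb, kept sites with at least 10 reads in their own state or none in the other, kept sites with a scaled level (reads times step) of at least 1000, and used the placement past gene midpoints. These used 10000 resamples and 200 placements.

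The tests were tried on simulated lists. In 20 pairs of lists without a difference, 2.27% of 220 tests fell under 0.05. Sites of the simulated lists were drawn independently, without the clusters of the listed sites, and many of these p-values were adjusted. This rate therefore does not apply to clustered lists. In 20 pairs with 80 sites planted on AP-1 motifs and 60 on chromosome X, both excesses were found in 20 of 20. The decoding returned the right reads for 1000 of 1000 simulated folds. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6, pysam 0.24.0 and matplotlib 3.10.9 were used.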

Results

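Capped 5′ ends of nascent RNA were mapped in proliferating and replicatively senescent IMR90 fibroblasts. The deposited lists are named for start sites of one state and not of the other, and are called senescent-only and proliferating-only here. The lists held 849 senescent-only and 400 proliferating-only sites on 23 chromosomes. A senescent-only site rested on a median of 32 reads in senescent cells (interquartile range 14 to 73, range 1 to 908), and a proliferating-only site on a median of 24 reads in proliferating cells (interquartile range 12 to 48.25, range 1 to 527). No read of the other state fell on 470 senescent-only sites (55.4%) and on 292 proliferating-only sites (73%). The remaining sites had up to 31 and 13 reads of the other state, so the lists also hold starts used in both states at unlike levels. Under 5 reads supported 8 and 7 sites. There were no values per replicate, so no value below has a spread between libraries.

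The first comparison asked how many sites each list held. Senescent-only sites outnumbered proliferating-only sites 2.12 to 1 (95% interval 1.88 to 2.40, exact binomial p = 1.3e-37). The ratio was 2.30 (1.99 to 2.66) for regions of sites joined within 500 bases, 2.09 (1.79 to 2.44) for regions joined within 10 kb, and 1.61 among sites with no read in the other state. The authors' folds ranged from 10.2 to 11420 in the senescent-only list, with a median of 296, and from 10.04 to 11576 in the proliferating-only list, with a median of 473. At a site with no read in the other state the fold is set by the reads of its own state and the pseudocount of 1, and such sites were more of the proliferating-only list. The medians of all sites differed by a permutation test (p = 1e-05, the smallest that the resamples can give), and the difference did not pass among sites with no read in the other state (permutation p = 0.26).

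Named genes with the most senescent-only sites were PTPRM, a receptor tyrosine phosphatase, and GTDC1, a glycosyltransferase-like protein, with 12 sites each. NALF1, an accessory factor of the sodium leak channel, held 11 and ANTXR1, a collagen-binding anthrax toxin receptor, held 10. RAD51B, which acts in homologous recombination, MGAT5, which branches N-glycans, the kinase gene STK32B and the kinase-anchoring gene PALM2AKAP2 held 9 each. CDCP1, a transmembrane glycoprotein, held 8 and MED15, a subunit of Mediator, held 7. The sites stood close together in some of these genes and apart in others. The 12 sites of PTPRM lay between 8116482 and 8142497 on chromosome 18, within a gene that spans 7566780 to 8406859, and formed 2 regions when joined within 10 kb. The 9 sites of MGAT5 formed 1 region between 135156237 and 135168540 on chromosome 2. The 9 sites of RAD51B, in contrast, formed 6 regions, as did the 11 of NALF1 and the 10 of ANTXR1, and the 9 of PALM2AKAP2 formed 5.

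The most proliferating-only sites lay in TENM4, a teneurin adhesion receptor, with 7. PLS3, an actin-bundling plastin on chromosome X, and PLXNA2, a semaphorin receptor, held 6 each. PCSK7, a proprotein convertase, SLC14A2, a urea transporter, PPP1R12B, a subunit of myosin phosphatase, and LRMDA held 5 each. NOS3, the endothelial nitric oxide synthase, and KCNH2, a potassium channel, held 4 each. The 6 sites of PLS3 formed 1 region between 114848660 and 114851406, and the 6 of PLXNA2 formed 1 region on chromosome 1 between 208202954 and 208204210. The 10 genes with the most sites took 11.3% of the senescent-only and 12.75% of the proliferating-only sites.

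**Figure D1:**
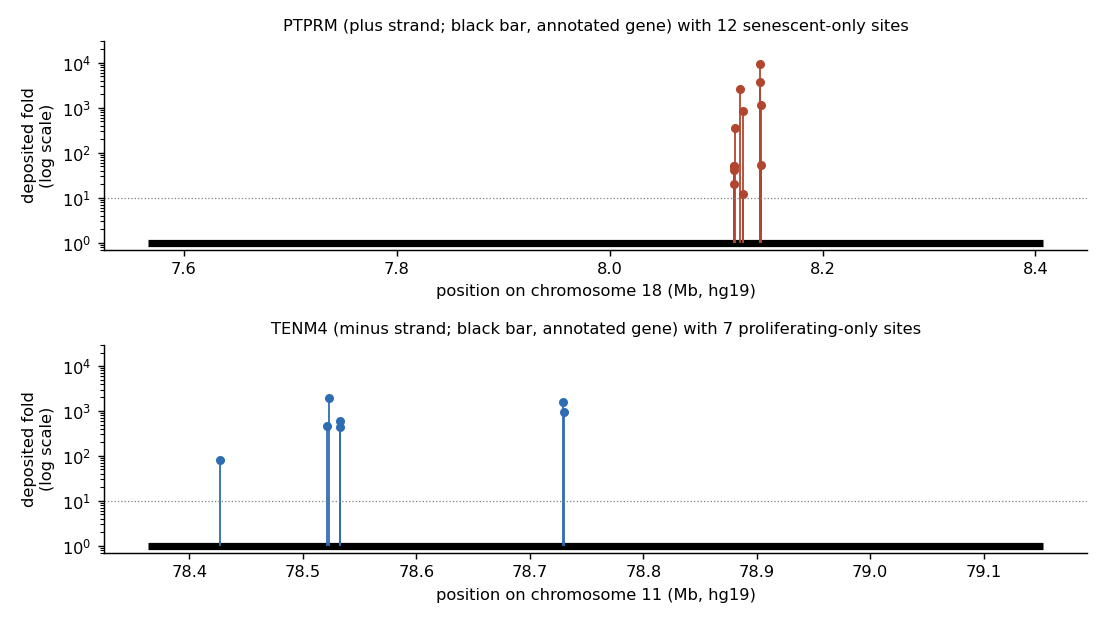
Positions (horizontal axis, Mb of hg19) and deposited folds (vertical axis, log scale) of the sites in the gene with the most sites of each list; each point is 1 site, the black bar is the annotated gene and the dotted line marks a fold of 10. The 12 senescent-only sites of PTPRM stand within 2 regions and the 7 proliferating-only sites of TENM4 within 3.

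The highest senescent-only fold, 11420, belonged to a site at 33500983 to 33501132 of chromosome 2, in LTBP1, which encodes a latent TGF-β binding protein. It had 348 reads in senescent and 0 in proliferating cells and lay 81 bases from an annotated start of an LTBP1 transcript, 329 kb from the 5′ end of the gene. A second LTBP1 site 97 bases from an annotated start had a fold of 8335. An intronic PTPRM site at 8141151 to 8141300 had a fold of 9287 with 283 reads, and the bases at its centre, from 8141210 to 8141240, read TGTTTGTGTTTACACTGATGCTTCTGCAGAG. The other sites of the top 10 lay in introns of MAPKAP1 (7285), STK32B (6990), RUNX3 (6104), RIMS2 (5546) and SMOC1 (5120), in an exon of STEAP1B (5776), and inside TRIP13 (6006). The TRIP13 site was 357 bases from a transcript start annotated to another gene. MAPKAP1 is a subunit of mTOR complex 2, RUNX3 a transcription factor, SMOC1 a matricellular protein and TRIP13 a mitotic checkpoint ATPase.

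The highest proliferating-only fold, 11576, belonged to an exonic site of SLC9A4, a sodium-proton exchanger, at 103130570 to 103130719 of chromosome 2, with 294 reads in proliferating and 0 in senescent cells. Its central bases, from 103130629 to 103130659, read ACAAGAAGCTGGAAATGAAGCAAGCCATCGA. Intronic sites of SYT1, a synaptic vesicle calcium sensor (fold 10631), and PLS3 (9883) came next. PPP1R12B held 3 intronic sites of the top 10 (6458, 5867 and 5828). The rest lay in an exon of UNC5CL (5513), at an annotated start inside EGF (5355), in an intron of KCNH2 (5158) and, with no protein-coding host gene, at 90699423 to 90699572 of chromosome 5 (4647), where ARRDC3 had the nearest transcript start at 20363 bases.

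The place of the sites relative to genes was compared next. Most sites of both lists were intronic, 704 of 849 senescent-only (82.9%, 80.2 to 85.3) and 288 of 400 proliferating-only (72%, 67.4 to 76.2). Random places on the same chromosome were 52.8% and 52.3% intronic, and 36.5% and 36.3% intergenic. A selection of sites inside genes before deposit could give this contrast and was not tested. The intronic share was higher among senescent-only sites (odds ratio 1.89, 1.41 to 2.53, adjusted Fisher's exact p = 5.1e-05). Within 1 kb of an annotated transcript start lay 74 senescent-only (8.72%, 7.0 to 10.8) and 67 proliferating-only sites (16.75%, 13.4 to 20.7), a lower share in the senescent-only list (odds ratio 0.475, 0.328 to 0.688, adjusted Fisher's exact p = 1.0e-04). Exonic shares of 8.36% and 10% did not differ past the threshold (adjusted exact p = 0.34). Intergenic sites numbered 0 and 5 (adjusted exact p = 0.0044), a difference that did not pass with protein-coding genes only (p = 0.20), in the 50% of sites with the highest fold (p = 0.32) or among sites with no read in the other state (p = 0.51).

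Both lists were nearly free of gene starts. Only 2 senescent-only and 3 proliferating-only sites lay within 5 kb of the 5′ end of a protein-coding gene (0.236% and 0.75%), where random places on the same chromosomes put 5.80% and 6.68%. Of the sites inside 1 coding gene and outside promoters, 629 of 682 senescent-only (92.2%, 90.0 to 94.0) and 257 of 290 proliferating-only sites (88.6%, 84.4 to 91.8) lay past the midpoint of the gene. The senescent-only list held 11 sites between 45% and 50% of gene length and 73 between 50% and 55%; the proliferating-only list held 11 and 16. The median position was 71.5% and 72.9% of gene length (difference -1.41 points, permutation p = 0.41). Random places drawn only past gene midpoints were 9.23% promoter and 82.5% intron for the senescent-only list, close to the observed shares (permutation p = 0.64 and 0.80). For the proliferating-only list they were 9.71% promoter and 81.6% intron, and the observed promoter share of 16.75% lay above and the intron share of 72% below (permutation p = 0.002 each, the smallest that the placements can give).

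**Figure D2:**
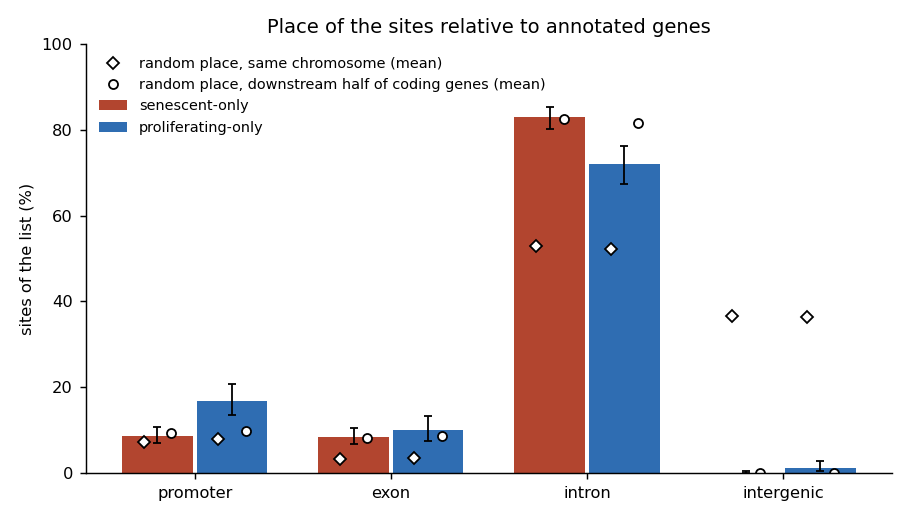
Percent of the sites of each list (vertical axis) by class of place (horizontal axis); bars are observed shares with Wilson 95% intervals, diamonds the mean of random places on the same chromosome and circles that of random places past the midpoint of coding genes. Promoter sites made up 8.72% of the senescent-only and 16.75% of the proliferating-only list.

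**Figure D3:**
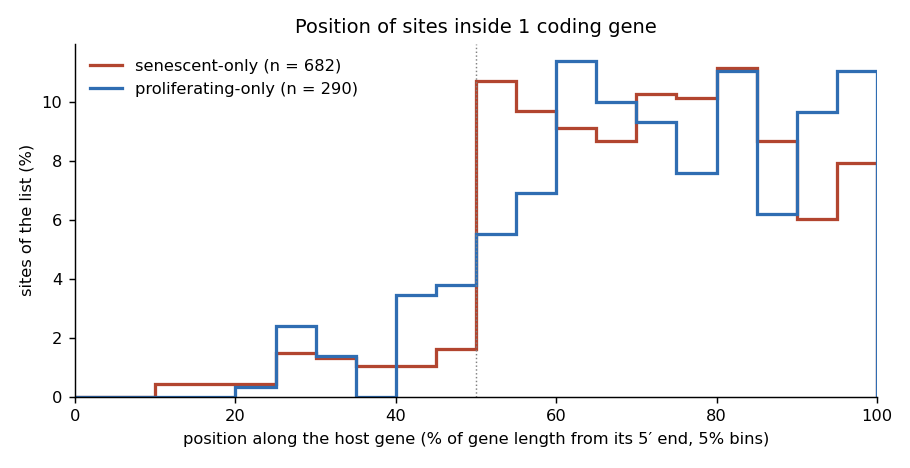
Percent of the sites of each list (vertical axis) along the host gene (horizontal axis, percent of gene length from the 5′ end in steps of 5%), for 682 senescent-only and 290 proliferating-only sites. The senescent-only line rises at the dotted line at 50%, from 11 to 73 sites.

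Sites of the same list clustered. Another site of the list lay within 10 kb of 535 senescent-only sites (63.0%) and 251 proliferating-only sites (62.75%), where random places on the same chromosome gave means of 5.49 and 1.19 sites (permutation p = 0.002 each, the smallest that the placements can give). The shares did not differ past the threshold (permutation p = 0.95), but both the shares and this comparison depended on which sites were counted. After joining within 500 bases the shares were 34.6% for senescent-only and 22.1% for proliferating-only regions (permutation p = 5.0e-04), and among sites with no read in the other state they were 41.3% and 55.8% (permutation p = 2.0e-04). In the 50% of sites with the highest fold they were 38.4% and 50% (permutation p = 0.0061). No senescent-only site overlapped a proliferating-only site or lay within 1 kb of one. Random places on the same chromosome gave means of 0.028 and 0.242 sites, so these counts set nothing apart. Every fold was above 10, so the same position could not enter both lists. Within 10 kb lay 2 senescent-only sites, against a mean of 2.29 for random places on the same chromosome (permutation p = 1). The mean was 8.85 for random places past gene midpoints (permutation p = 0.014). Those places were drawn independently in less space, while the listed sites clustered. That p-value therefore does not show that the lists avoid each other.

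Host genes numbered 410 for the senescent-only and 220 for the proliferating-only list, and 16 genes held sites of both, where random places past gene midpoints, drawn for the regions joined within 10 kb, gave a mean of 27.1 shared genes (18 to 37.0, permutation p = 0.028). Every drawn place fell in a coding gene, as 92.7% and 90.5% of the listed sites did with 1 kb upstream included. The places were also drawn independently, while several listed regions could share a gene, as the 6 senescent-only regions of RAD51B did. The draws may thus reach more genes and share more of them, so this p-value does not show that the lists avoid each other's genes. The shared genes were ATXN1, BCAS3, CACNA1C, CAMTA1, CELF4, FRMD4A, GPC6, HIVEP3, KLHL29, MAP3K7CL, MARCHF1, NRP2, NXN, PALLD, RAD51B and SYT1, of which most were named after their values were seen. RAD51B held 9 senescent-only sites between 68675017 and 69129415 of chromosome 14 and 4 proliferating-only sites between 69104182 and 69105533.

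The lists differed in their spread over chromosomes (chi-square 112, permutation p = 1e-05, the smallest that the resamples can give). Chromosome X held 13 senescent-only (1.53%) and 33 proliferating-only sites (8.25%; odds ratio 0.173, 0.083 to 0.343, adjusted Fisher's exact p = 7.8e-07), and the difference passed after joining within 10 kb (adjusted p = 0.040). Chromosome 1 held 43 and 47 sites (5.06% and 11.75%, adjusted exact p = 5.9e-04), a difference that no longer passed after joining within 500 bases (adjusted p = 0.060). Shares were higher in the senescent-only list on chromosomes 4, 5, 8 and 13 (adjusted exact p = 0.039, 0.0028, 0.037 and 0.015) and lower on chromosome 19 (adjusted p = 0.037). Single chromosomes other than 1 and X were not tested after joining, so clusters may account for these calls.

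**Figure D4:**
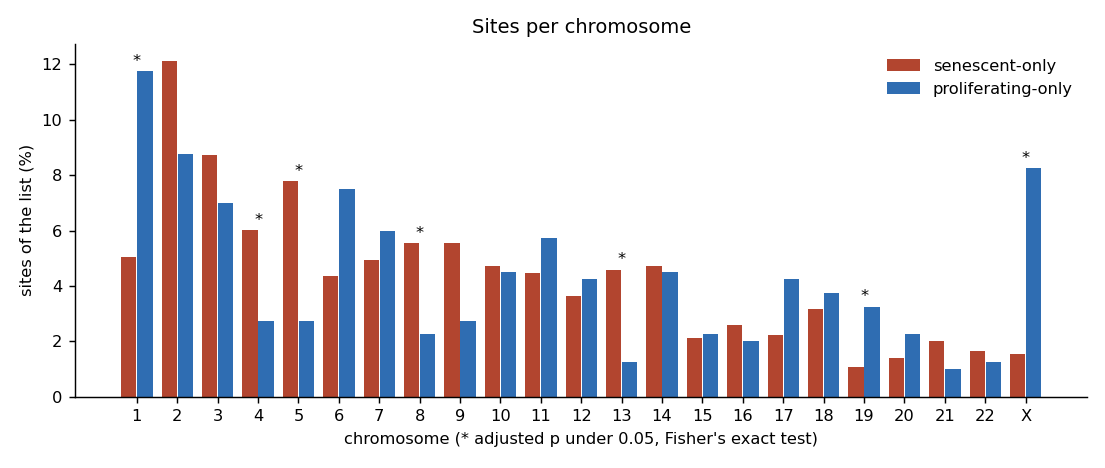
Percent of the sites of each list (vertical axis) on each chromosome (horizontal axis); asterisks mark an adjusted Fisher's exact p under 0.05. Chromosome X takes 1.53% of the senescent-only and 8.25% of the proliferating-only sites.

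Sequence around the sites was compared because AP-1 motifs, bound by FOS and JUN family factors, and CpG-rich DNA mark different kinds of starts. An AP-1 motif lay within the central 200 bases of 155 senescent-only sites (18.3%, 15.8 to 21) and 39 proliferating-only sites (9.75%, 7.21 to 13.1). Both shares lay above the 3.06% and 3.05% of random places on the same chromosome (permutation p = 0.002 each, the smallest that the placements can give). The share was higher in the senescent-only list (odds ratio 2.07, 1.41 to 3.09, adjusted Fisher's exact p = 2.3e-04), while shuffles of each site's own sequence that kept its dinucleotides gave an odds ratio of 1.58 (1.51 to 1.66). TATA boxes were present at 14.6% and 14% of sites (adjusted exact p = 0.80). Median GC content was 45.5% in the senescent-only and 47.5% in the proliferating-only list (permutation p = 1.6e-04), which did not pass after joining within 500 bases (p = 0.21). The median CpG observed-to-expected ratio was 0.186 and 0.249 (permutation p = 3.0e-05). GC and CpG were not compared among intronic sites alone. These differences thus cannot be told apart from the higher promoter share of the proliferating-only list.

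**Figure D5:**
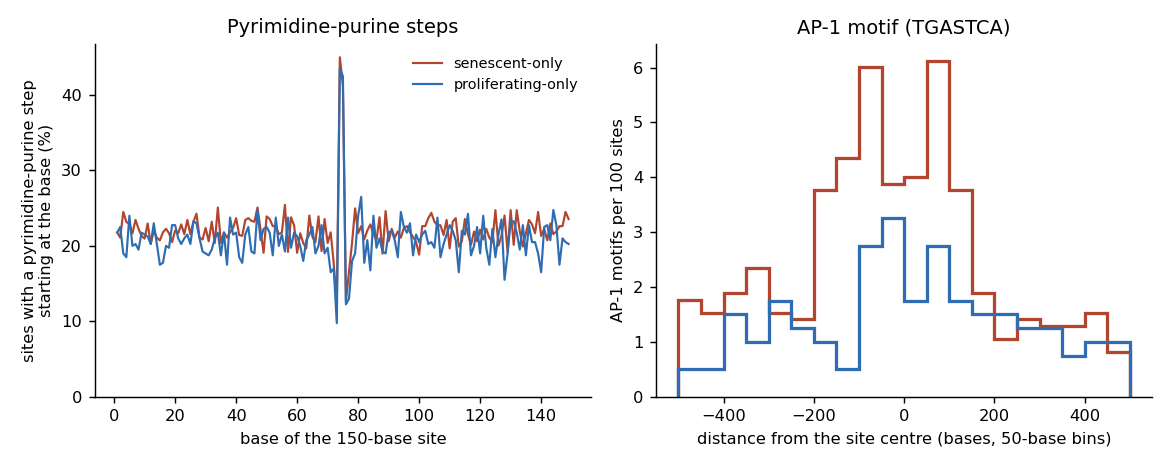
Left, percent of sites (vertical axis) with a pyrimidine followed by a purine at each base of the 150-base site (horizontal axis); right, AP-1 motifs per 100 sites (vertical axis) in 50-base bins of distance from the site centre (horizontal axis). Steps reach 45% of senescent-only and 43.5% of proliferating-only sites at the centre, and AP-1 motifs reach 6.12 per 100 senescent-only sites and 3.25 per 100 proliferating-only sites.

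The 9 gene lists showed no difference that passed correction, either between the lists of sites (adjusted Fisher's exact p of 0.85 or more) or against random genes of like length (adjusted p of 0.50 or more). Among 47 genes of the extracellular matrix and fibroblast identity, 4 held 10 senescent-only sites and 1 held a proliferating-only site. They included COL8A1, a short-chain collagen, with 4 senescent-only sites (highest fold 296), and LOXL2, which crosslinks collagen, with 4 (1182). COL4A1 and PDGFRA held 1 each (329 for both), and FBLN1 held the proliferating-only site (10.5). Against random lists the count of 4 genes had a mean of 1.24 and an unadjusted p of 0.064. Among 50 secreted and inflammatory factors of senescence, 2 genes held 6 senescent-only sites and none held a proliferating-only site (0). IGFBP7, an insulin-like growth factor binding protein, had 4 between 57901396 and 57919954 of chromosome 4 (highest fold 1707), and TGFB2, a TGF-β ligand, had 2 on chromosome 1 (1346 and 559).

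Among the interferon response genes, IRF1 held 2 senescent-only sites (756 and 49.6). The list as a whole had an unadjusted p of 0.034 and an adjusted p of 0.50 against random genes. The IRF1 sites, at 131794911 to 131795515 of chromosome 5, lay in an annotated gene span of 68.3 kb that includes extended transcripts. Among 40 AP-1, C/EBP, NF-kB and immediate early factors, RUNX1 held 2 senescent-only sites (144 and 31.2), BACH1 and MAFK held 1 each (36.0 and 17.7), and RUNX2 held 1 proliferating-only site (1143). Of 53 cell cycle and replication genes, HMGB1, a chromatin protein, held 2 senescent-only sites (1018 and 28.0), in an annotated span of 160.9 kb that also includes extended transcripts. Among 50 chromatin regulators, EHMT1 and HDAC9 each held 1 senescent-only site and HDAC4 held 1 proliferating-only site. No site lay in the 30 cell cycle arrest genes, the 32 housekeeping genes or the 29 markers of other cell types (0 sites in each). Of these genes, 20, 14 and 19 were longer than 10 kb. Random lists of like length held a mean of 0.358, 0.183 and 0.482 genes with a senescent-only site, so that a count of 0 does not set these lists apart.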

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

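The results for 10-kb joining, reads, scaled level and placement past gene midpoints were added after the data were examined. No paired analysis was possible because the lists hold no values per sample. No replicate could be left out for the same reason. Over all results and alternatives, with the lowest and highest value over left-out chromosomes taken for each result, 234 values kept their direction and side of the threshold, 8 lost and 2 gained a call, and 18 changed direction. Over all single chromosomes left out, 21 values changed direction, none past the threshold. The number of sites, clustering against random places in both lists where tested, the chromosome distribution, the promoter and intron shares, CpG content and AP-1 kept direction and call under the alternatives run, chromosomes left out included. The senescent-only share of sites ranged from 61.7% to 70.0%, and the AP-1 odds ratio from 1.85 to 2.53. The 50% of sites with the highest fold and the summed width (68.1%) fix the number result by construction, and 10-kb joining rules out clustering. Tests that need a strand from the files were not run.

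Calls that ended were the intergenic difference in the sites with the highest fold (-0.490 points), with protein-coding genes only (-2.20) and with no read in the other state (-0.342), the fold difference with no read in the other state (-72.1), the GC difference after joining within 500 bases or 10 kb (-1 point in each), and the chromosome 1 odds ratio in the same settings (0.497 and 0.521). Fewer sites were tested in all but one of these; beyond that, the cause was not tested. The share of senescent-only sites within 10 kb of the other list, 0.236%, passed as low against places past gene midpoints (permutation p = 0.020). Those places were drawn independently, while the listed sites clustered, so this call does not show that the lists avoid each other.

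The difference between the lists in clustering (0.265 points) was called after joining within 500 bases (12.5 points) and turned and was called in the sites with the highest fold (-11.6) and with no read in the other state (-14.5). It also turned, uncalled, in 12 left-out chromosomes, most without chromosome 3 (-1.52). Direction changed, with no call in either setting, for the share within 10 kb of the other list after 10-kb joining (0.196%), with at least 10 reads (0.256%) and without chromosome 13, 18 or 22 (0.247%, 0.243% and 0.240%), the exon difference after 10-kb joining (0.146 points), the position along genes without chromosome 18 (0.361 points) or 3 (0.305), and the TATA odds ratio after joining within 500 bases (0.968) or 10 kb (0.861), on autosomes, that is without X (0.9999), and without chromosome 15 (0.9998). Genes widened by 50 kb turned the secreted (-0.339 points), cell cycle (-0.832) and matrix lists (-0.802). The AP-1 factor list turned in the sites with the highest fold (-0.532), with no read in the other state (-0.370) and without chromosome 21 (-0.149), and the chromatin list without chromosome 2 (0.290). The cause was not tested. Depth limits single sites, as 68 senescent-only and 58 proliferating-only sites had under 10 reads.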

Other observations

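Tests on the strand of starts, on paired starts, on orientation and on the gene midpoint were chosen after the result was seen, as were the GC bins, the counting noise of shuffled motifs and the shuffled sequences. Transcription starts usually fall on a pyrimidine followed by a purine. Such a step began at base 74 of the site in 45% of senescent-only and 43.5% of proliferating-only sites, and at base 75, where a start on the minus strand would put it, in 41.2% and 42.5%, while bases more than 10 away from the centre had means of 22.0% and 20.8%. Over both lists 41.6% of sites had the minus-strand step, so the + written at every site may be a placeholder. One of the steps was present in 86.2% of senescent-only (83.7 to 88.4) and 86% of proliferating-only sites (82.3 to 89.1), against means of 44.1% and 41.7% for 2 neighbouring bases away from the centre. It was used to assign a strand, so some strands are assigned by chance steps.

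Neighbouring senescent-only sites 50 to 300 bases apart pointed away from each other in 101 of 109 pairs on opposite strands (92.7%, 86.2 to 96.2, exact binomial p = 1.3e-21), at a median distance of 153 bases. Of the proliferating-only pairs 39 of 60 did so (65%, 52.4 to 75.8, exact binomial p = 0.027), and with 1 pair per region joined within 10 kb 33 of 52 did (63.5%, p = 0.070), so for that list the excess is open. The lists differed (odds ratio 6.71, 2.60 to 19.1, Fisher's exact p = 1.0e-05), also with 1 pair per region (90 of 98 against 33 of 52, p = 3.5e-05). Only neighbouring sites were paired, so after a close pair pointing apart the next gap tends to run from a plus-strand to a minus-strand start. Wider pairs therefore tend to point toward each other by construction, and their values are no separate result. At wider spacing the pairs did go the other way. Between over 300 and 1000 bases 9 of 37 senescent-only (24.3%, adjusted exact p = 0.0077) and 4 of 18 proliferating-only pairs on opposite strands pointed apart (22.2%, adjusted exact p = 0.042), and up to 10000 bases 10 of 33 (30.3%, adjusted exact p = 0.042) and 3 of 8 (37.5%, adjusted exact p = 0.73). A hypothesis is that many senescent-only sites may be the 2 starts of divergent elements such as enhancers inside genes. PTPRM gives an example, with a minus-strand step at the site from 8141151 and a plus-strand step at the site from 8141304, although another of its pairs, at 8117180 (plus) and 8117233 (minus), pointed inward. A further hypothesis, that starts follow the strand of the host gene, was not borne out. The step lay on the gene's strand at 301 of 585 senescent-only sites (51.5%, 47.4 to 55.5) and 117 of 248 proliferating-only sites (47.2%, 41.1 to 53.4). Pairs on opposite strands inside a gene and strands assigned by chance steps pull these shares toward an even split. A bias in orientation could thus be masked.

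The sites stood past gene midpoints and away from gene 5′ ends in both lists. For the senescent-only list a filter on gene position before deposit may account for this. The number of its sites rose 6.64-fold from the 5% of gene length before the midpoint to the 5% after it. A smooth gradient along genes would not give such a step. In the proliferating-only list the same bins held 11 and 16 sites, a rise that a smooth gradient could give. No step was thus seen there, and a filter on that list stays open. Other gene models than those used by the authors would blur such a step, but the same models were used here for both lists. How starts nearer to gene 5′ ends or outside genes differ between the states cannot be read from these lists. No biological explanation of the position was tested.

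The excess of senescent-only sites was weighed against depth and clusters. The steps in the folds put the senescent data at 1.2 times the depth of the proliferating data, and among sites with a scaled level of at least 1000, far above what few reads give, the ratio of site numbers was 2.34 (1.96 to 2.79). This argues against depth as the whole cause, provided both states were scaled to the same total. Joining within 10 kb left a ratio of 2.09 (1.79 to 2.44), which argues against clusters counted many times. Differences between libraries in the yield of capped RNA stay open, because no value per library was used. State and population doubling cannot be told apart, because every proliferating library came from a lower doubling than every senescent one. The excess may lie in any of these.

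The higher AP-1 share of senescent-only sites was kept over regions joined within 10 kb (odds ratio 2.20, 1.34 to 3.74) and among intronic sites alone (2.14, 1.37 to 3.43), which argues against clusters and against the share of sites near annotated starts. Base composition stays open. Of 200 shuffled versions of the motif 30 gave an odds ratio at least as large. This was more than the share set beforehand as a sign of base composition. The shuffled motifs had few hits, however, and counting noise alone would send 21 of them (13 to 29) that far. Noise alone would thus also exceed that share, and the count of 30 lies just above the range of noise. The count therefore does not decide. Of the 200, 13 differed between the lists with an adjusted Fisher's exact p under 0.05, all 13 more frequent at senescent-only sites, which goes with a wider difference in sequence. The odds ratio within 5 bins of GC content was 1.98 (1.36 to 2.87). Dinucleotide-preserving shuffles of the sites, which keep the bases of the motifs they hold, gave 1.58 (1.51 to 1.66). That lies inside the interval of the observed 2.07 (1.41 to 3.09), so composition may account for part or all of the odds ratio. Composition does not give the motif's presence or the whole gap between the shares. The shuffles held the motif at 4.97% of senescent-only and 3.20% of proliferating-only sites, against 18.3% and 9.75% observed.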
